A study of Homo sapiens with 6 samples.

How the data were processed

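RNA of the human breast cancer line MDA-MB-231 was hybridised to 6 Affymetrix arrays of 54675 probe sets each. The cells carried either the empty pcDNA3.1 vector or parvin-beta (PARVB), and each transfectant was grown in 3 cultures. An extraction label of the PARVB array in 3D collagen writes PARVB3 and was read as PARVB. The arrays therefore form 6 groups of 1 array. Per the labels, 8 µg of total RNA went through 2 rounds of in vitro transcription, the second from randomly primed cDNA, a route that can shorten the product and weight signals toward the 3' end of transcripts.

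The authors made the values with MAS5, which the submitters' processing notes name without a version. The deposited value table holds a linear signal intensity per probe set and array. Its 2% trimmed mean is 150 on each of the 6 arrays, so the authors scaled every array by 1 factor, and no further scaling was applied. This scaling leaves the shape of the distribution free. The median intensity was 47.6 and 45.5 (vector, PARVB) on 2D collagen, 24.9 and 31.1 in 3D collagen and 79.1 and 81 in Matrigel. The share of probe sets under a signal of 10 was 20.7% and 21%, 31.9% and 27.6%, and 10.4% and 10.2% in the same order. The 3 deposited pairwise tables list the probe sets that the authors called changed between PARVB and vector in 1 culture. They give a signal log ratio in log2 per the labels, a 1-sided change p-value that the authors' software computed from the probe pairs of 1 array against 1 array, and a detection call (present, marginal or absent) with its p-value per array. They list 1916 probe sets for 2D collagen, 5685 for 3D collagen and 2847 for Matrigel, and their intensities equal those of the value table within 0.05. The number of arrays limits the precision.

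Gene names came only from the tables of both 3D cultures, since no other file ties probe sets to genes. Of their 7562 probe sets, 6408 carried 1 symbol (4722 symbols in all), 204 carried several and 950 carried none. Symbols were updated to current ones where a synonym allowed it. The symbol column of the 2D collagen table was set aside: of 869 probe sets that a 3D table also names, 37 had the same symbol there, and the median correlation over the 6 arrays between probe sets of 1 symbol was 0.09 under its names against 0.66 under those of the 3D tables. All 970 probe sets shared by the 3D tables had the same symbol in both. Every named gene is therefore one that the authors called changed by PARVB in at least 1 3D culture, so its size in those cultures is not independent of that choice. A design with 1 probe set per gene had been fixed before the data were examined; with 11.7% of probe sets named, the counts below are of probe sets instead, and a run with 1 probe set per named gene stands among the alternatives. Probe positions were not available.

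Signals were analysed as log2 of the intensity plus a pseudocount of 13, the 25th percentile of all signals. The 62 control probe sets were left out, and the 27297 others whose mean log2 signal lay above the median were kept. A linear model with culture and transfectant as terms was fitted to the 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes without trend or robust settings). It leaves 2 residual degrees of freedom, to which the prior of the moderation (prior variance 0.0693) adds 5.54. The PARVB term treats the 3 cultures as the repeats of the PARVB difference, and each culture difference treats both transfectants as its repeats. All limma tests are 2-sided, and a Benjamini-Hochberg adjusted p under 0.05 was called. On simulated data, 200 of 27297 probe sets were changed, in equal parts by 2-, 4-, 8- and 16-fold. There the fit recovered 12% of the 2-fold and 98% of the 4-fold PARVB changes, and 2% and 74% of those between cultures. It also called 14 and 10 unchanged probe sets. The adjusted threshold depends on how many probe sets change and by how much, so these shares need not hold for the 6 arrays. Within a culture there is 1 array per transfectant and no test is possible; probe sets with a log2 difference of at least 1 (2-fold) were counted, and the authors' calls are quoted as theirs. Their detection calls and the signals at or under the pseudocount were set beside the named genes after the results were seen. Overlaps between cultures were set beside the product of the shares, the number independent lists would give.

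The 24 gene lists were fixed before the data were examined: PPARG targets, cholesterol synthesis, fatty acid synthesis, focal adhesion genes around ILK, PINCH and the parvins, integrins, epithelial and mesenchymal genes, proliferation, hypoxia, glycolysis, extracellular matrix components, matrix proteases and their inhibitors, cytokines and NF-kB targets, interferon response, unfolded protein and amino acid stress, heat shock, immediate early genes, YAP and SRF cytoskeletal targets, oxidative phosphorylation, ribosomal proteins, and markers of fibroblasts, leukocytes, endothelium and adipocytes. The 20 lists with at least 5 of their genes among the 4268 named and tested genes (the brightest probe set of each) were compared with the other named genes by camera with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated one. With an estimated correlation camera tests on the 2 residual degrees of freedom, so few lists can pass there, whatever their correlation. Within a culture, the median log2 difference of a list was placed among 10000 random lists of the same size drawn from 10 bins of mean signal; a median above percentile 97.5 or below 2.5 is called outside the random lists, which is a description and not a test.

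Genes named in the text follow a rule fixed in advance. For each limma comparison they are the 10 highest and 10 lowest differences among named genes that passed, filled up, where fewer passed, with genes of the same sign in every pair and the largest smallest-pair difference. For each culture they are the 8 highest and 8 lowest differences among probe sets that the authors' table calls the same way. Added to these are the probe sets at least 2-fold different the same way in the 3 cultures, the 2 highest and 2 lowest members of a reported list, and PARVB, PPARG, CDK9, ILK, PARVA and LIMS1; LIMS1 is not named in the files. The Matrigel to 2D collagen comparison was fixed as a count with gene lists.

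Alternatives fixed in advance were pseudocounts of 1 and of 50.1 (the median of all signals), no filter, a filter at the 75th percentile, quantile normalization of the 6 arrays, the mean over a gene's probe sets, trend and robust moderation, no culture block, leaving out each pair or array, thresholds of 1.5-fold and 3-fold, the authors' tables, an estimated correlation for camera, and other probe sets of a named gene. Chosen after seeing the data were the fits without both Matrigel or both 3D collagen arrays, 1 probe set per named gene, the focal adhesion list without PARVB, the overlap without the 3D collagen pair, and the scaling and pseudocount runs of the numbers of named genes and of lists that went opposite ways between cultures. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.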

Results

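The study asked which genes parvin-beta (PARVB), a focal adhesion protein that binds integrin-linked kinase, raises or lowers in MDA-MB-231 cells, and how far these genes depend on the surroundings of the cells. MDA-MB-231 is an established triple-negative breast cancer line. Vector and PARVB transfectants were each grown on plastic coated with bovine type I collagen at 60 µg/ml (2D collagen, 5 to 7 days), inside a gel of 1.5 mg/ml bovine type I collagen (3D collagen, 7 days), or in 40% growth-factor-reduced Matrigel over a base of 80% (Matrigel, 7 days). Serum was 10% throughout. Each of the 6 groups has 1 array, so a PARVB difference within a culture has no error of its own. As a sign of RNA quality, the ratio of 3' to 5' signal of the ACTB control probe sets was 1.08 and 1.06 (vector, PARVB) on 2D collagen, 1.39 and 2.09 in 3D collagen and 1.05 and 1.1 in Matrigel. For GAPDH it was 0.854 and 0.851, 1 and 1.45, and 0.959 and 1.01.

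The PARVB signal was higher in the transfectant in each culture. Its named probe set, 37965_at, read 45.8 in vector and 189.8 in PARVB cells on 2D collagen, 20.1 and 239.1 in 3D collagen, and 128.4 and 236.7 in Matrigel. The log2 differences were 1.79, 2.93 and 0.82. The authors' deposited table calls all 3 increased, with signal log ratios of 1.3, 3.2 and 0.4, so both measures were smallest in Matrigel. It calls the vector array absent, that is not above background, on 2D collagen and in 3D collagen, and present in Matrigel. An extraction label of the PARVB array in 3D collagen writes PARVB3 for the cells, where its other labels write PARVB; it was read as the same transfectant, and whether it names another clone is not in the files. A probe set outside the transfected coding sequence would not read the transgene, and its position is not in the files. The log2 difference of PARVB, averaged over the cultures, was 1.85 (SE 0.36) and did not pass the adjusted threshold (limma, adjusted p = 0.785). Its relative PARVA (alpha-parvin) differed by 0.48, -0.72 and -0.81 at 217890_s_at and by 0.08, -0.09 and -0.59 at 222455_s_at, in the same order of cultures. ILK, the kinase-like partner of both parvins, differed by 0.16, 0.88 and 0.4. PPARG, a nuclear receptor that governs lipid genes, differed by 0.86, -0.08 and 2.29, and its signal in Matrigel was 32.8 in vector, where it was called absent, and 210.5 in PARVB cells. CDK9, a kinase of transcription elongation, differed by -0.19, -0.27 and 0.62.

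Across the 3 cultures, 20 named genes stood out as different between PARVB and vector cells in the same direction, 10 lower and 10 higher, and none of them passed the test. TNC, the matrix glycoprotein tenascin C, was lower with PARVB by log2 differences of -1.11 on 2D collagen, -3.77 in 3D collagen and -3.05 in Matrigel (average -2.64, SE 0.45). A second TNC probe set gave -0.8 in 3D collagen and 0.08 in Matrigel. CPE, which trims peptide hormones, was lower by -1.07, -4.02 and -1.8, and COL6A3, a collagen VI chain, by -0.8, -1.97 and -0.92. PTN (pleiotrophin, a secreted growth factor) had differences of -1.02, -2.32 and -0.74, and the lactate and pyruvate carrier SLC16A7 of -1.69, -0.95 and -2.18. CST7, AGO2, CCNG2, LNPEP and VDR, the vitamin D receptor, completed the lower group with averages from -1.37 for CST7 to -0.83 for VDR. Other probe sets were nearer to 0 in some cultures. AGO2 gave -0.04 and -0.07 on 2D collagen (-1.15 at the named probe set) and CPE -0.14 (-1.07), while in Matrigel LNPEP gave 0 (-0.76) and VDR 0.12 (-0.89). On 2D collagen the other 2 of PTN gave -0.39 and -0.48 (-1.02). On the higher side, CSF2RA, a chain of the receptor for granulocyte-macrophage colony-stimulating factor, was higher by 1.51, 2.77 and 2.56. Its other 2 probe sets past the filter gave -0.1 and -0.15 on 2D collagen and 0.24 and 1.39 in Matrigel, so they did not share its difference on 2D collagen. The RNA-binding protein RBPMS was higher by 1.4, 1.44 and 1.31. NUP210, a nuclear pore protein, had differences of 0.98, 2.47 and 1.71, GATA2, a transcription factor, of 1.13, 0.9 and 1.2, and CST6, a protease inhibitor, of 0.97, 1.83 and 0.89. CDK15, PRKCZ, CEMIP and FLJ11151 were also higher in the 3 cultures, with averages of 1.14, 1.07, 1.16 and 0.92. The authors' tables give detection calls only for probe sets listed as changed. Among these, CSF2RA, CPE, SLC16A7 and CST7 were called absent on both Matrigel arrays, PRKCZ on both 3D collagen arrays and CST6 on both 2D collagen arrays, so those differences rest on signals not called above background. The vector array alone was called absent for NUP210 in the 3 cultures, CSF2RA in 3D collagen, CDK15 and CST6 in Matrigel and FLJ11151 on 2D collagen. The PARVB array alone was called absent for TNC and COL6A3 in both 3D cultures, CPE in 3D collagen and SLC16A7 on 2D collagen. The sizes of these differences are therefore not exact. Where 1 array reads under the pseudocount of 13, the pseudocount sets the size of the difference, as for TNC (2.7) and CPE (7.7) in PARVB cells in 3D collagen and CSF2RA (8.1) in vector cells in Matrigel.

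**Figure D1:**
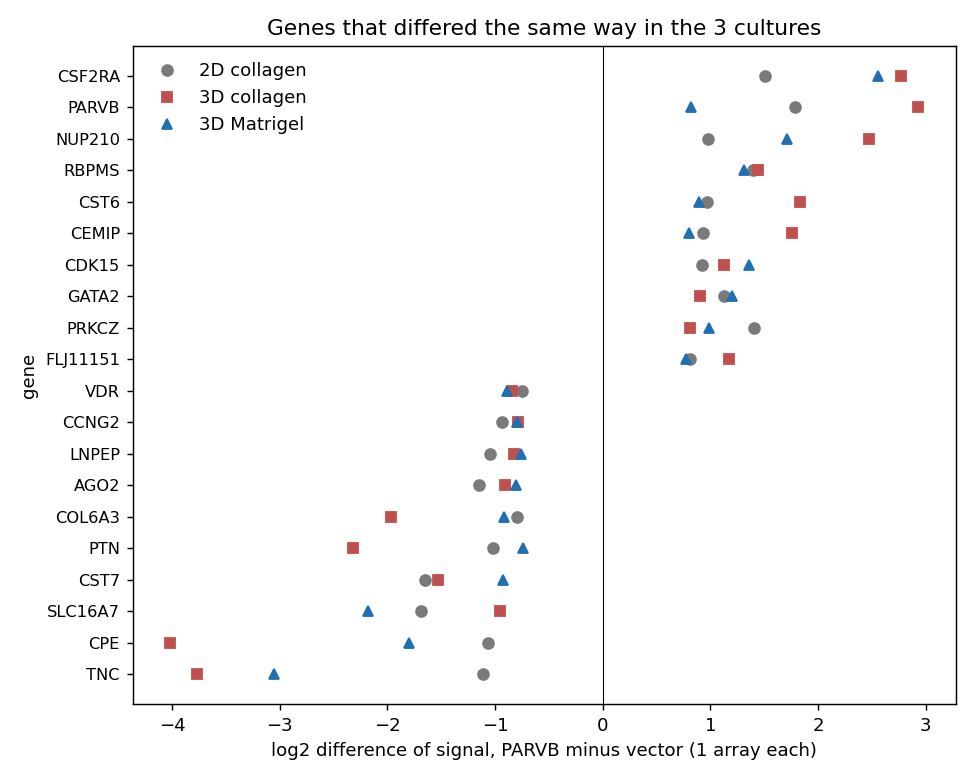
Log2 difference of signal between PARVB and vector cells (x axis, 1 array each) for the 20 genes named for the comparison across cultures (y axis), with 1 symbol per culture: circles for 2D collagen, squares for 3D collagen and triangles for Matrigel. TNC spans -3.77 to -1.11 and CSF2RA 1.51 to 2.77; all 20 genes lie on the same side of 0 in the 3 cultures, which is how they were chosen.

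By limma, 0 of 27297 probe sets passed the adjusted threshold for the PARVB term; the smallest adjusted p was 0.785, and 1661 (6.1%) had an unadjusted p under 0.05. The PARVB differences of separate cultures had little in common: across the 27297 probe sets, which are not independent replicates, Pearson's r was 0.03 between 2D and 3D collagen (Spearman's rho 0.03), 0.03 between 2D collagen and Matrigel (rho 0.02) and 0.16 between 3D collagen and Matrigel (rho 0.16).

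Tested as groups across the 3 cultures with camera, 6 of the 20 lists differed from the other named genes at the preset correlation. With an estimated correlation none of these 6 calls held, with an adjusted p = 0.946 for the interferon, epithelial, PPARG target and focal adhesion lists and an adjusted p = 0.962 for the ribosomal and hypoxia lists. That setting tests on 2 residual degrees of freedom in every comparison. The focal adhesion list had an estimated correlation of -0.06, under the preset 0.01, yet its unadjusted camera p went from 0.000425 to 0.0644. The loss of calls therefore cannot decide whether correlation within the lists made them. At the preset correlation, the interferon response list was higher with PARVB (adjusted p = 4.41e-08; median log2 difference 0.46 over 21 genes). IFI27 and OASL, both interferon-induced genes, led it with averages of 1.42 and 0.87, while HLA-E stood at 0 and HLA-F at 0.2. The epithelial list was higher (adjusted p = 0.00425; median 0.38 over 8 genes), led by the keratin genes KRT7 at 0.84 and KRT8 at 0.58. The PPARG target list was higher (adjusted p = 0.00584; median 0.33 over 12 genes), with PPARG itself at 1.02 and the lipid droplet protein PLIN2 at 0.64. The focal adhesion list was higher (adjusted p = 0.00425; median 0.28 over 14 genes), and it holds PARVB; without PARVB its adjusted p was 0.0598. The ribosomal protein list was higher (adjusted p = 0.00425; median 0.33 over 20 genes) and the hypoxia list lower (adjusted p = 0.0441; median -0.26 over 19 genes), the latter with LOX at -0.84 and ANKRD37 at -0.67. No single member of these lists passed over all genes; adjusted over the list alone, 1 focal adhesion gene (PARVB, higher) and 2 matrix component genes (TNC and COL6A3, lower) passed. Only genes that the authors called changed in a 3D culture carry a name, so the direction of a list in those cultures is not independent evidence.

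Without the 3D collagen pair the ribosomal and hypoxia calls ended (adjusted p = 0.748 for each), without the Matrigel pair the PPARG target (0.285) and epithelial (0.12) calls ended, without the 2D collagen pair the hypoxia call ended (0.0826), and with quantile normalization the ribosomal (0.876) and hypoxia (0.0997) calls ended. The other 14 lists did not pass; of these, cholesterol synthesis had a median of -0.34 (adjusted p = 0.131) and YAP and SRF targets of 0.04 (0.131), immediate early genes of 0.26 (0.455), unfolded protein and amino acid stress of 0.08 (0.647), oxidative phosphorylation of 0.04 (0.703), matrix proteases of -0.09 (0.715), matrix components of 0 (0.778), cytokines of 0.02 (0.818), mesenchymal genes of 0 (0.926) and fatty acid synthesis of -0.03 (0.926). The median and the direction of the test had opposite signs for glycolysis (median -0.14, adjusted p = 0.715), heat shock (0.07, 0.703), integrins (-0.17, 0.818) and proliferation (-0.05, 0.715).

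On 2D collagen, where the pair was most alike, genes of the cytokine and NF-kB list were lower with PARVB. CXCL8 (interleukin 8) read 375.7 in vector and 71.9 in PARVB cells, a log2 difference of -2.19, and CXCL1, another neutrophil attractant, differed by -1.47. Of this list, 12 of 13 members were below 0 (median -0.44, percentile 0 of the random lists). CEBPD, a transcription factor of inflammatory genes, differed by -1.48, SERPINB2, an inhibitor of urokinase, by -1.8, and SCD, the stearoyl-CoA desaturase, by -2.01, with an average of -0.51 over its 4 other probe sets. SNAP91, hCG_2003663, SLC16A7 and NUDT14 were lower by -1.86, -1.69, -1.69 and -1.59. The higher genes besides PARVB were NUP210 (1.49 at 213947_s_at), RBPMS (1.4), CFAP45 (1.15), ADM, the vasodilator peptide adrenomedullin (1.15), the metastasis suppressor KISS1 (1.11), VGLL3 (1.06) and CST6 (0.97); the other probe sets of NUP210 and RBPMS averaged 0.79 and 0.57. The authors' table calls 8 of these 16 probe sets absent on both arrays: SCD, SNAP91, hCG_2003663 and NUDT14 on the lower side, and NUP210, CFAP45, KISS1 and CST6 on the higher side. Their differences rest on signals not called above background. The vector array was called absent for PARVB and the PARVB array for SLC16A7. The cholesterol synthesis list had a median of -0.19 (12 of 13 members below 0; percentile 1.5) and hypoxia of -0.16 (percentile 0.8, and 3.8 with quantile normalization), and the unfolded protein and amino acid stress list was on the higher side (0.18; percentile 99.5), with SLC7A5 at 0.49 and SLC3A2 at 0.38. In all, 471 probe sets (1.73%) were at least 2-fold different, 211 higher and 260 lower with PARVB. The authors' table calls 603 increased and 1313 decreased here.

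In 3D collagen the PARVB differences were larger, with interferon response and proliferation genes on the higher side and matrix protease, hypoxia and cholesterol synthesis genes on the lower side. This is the pair whose PARVB array had ACTB and GAPDH 3' to 5' ratios of 2.09 and 1.45. NPPB, which encodes B-type natriuretic peptide, read 10.1 in vector and 1563.7 in PARVB cells (log2 difference 6.09), and TMEFF2, a transmembrane protein, 23.3 and 796 (4.48). NUP210 (3.55), MTSS2 (3.49), RPL37A (3.45), ATN1 (3.31), FKBP8 (3.2) and F11R, a tight junction adhesion molecule (3.17), were the next highest; the other probe sets of F11R averaged 0.09, and those of FKBP8 gave 1.13. On the lower side CPE (-4.02) and TNC (-3.77) were followed by APBA2 (-3.12), SPP1 (osteopontin, -2.93), the collagenase MMP1 (-2.71), SHISA2 (-2.66), CLEC2B (-2.66) and KCTD12 (-2.65). MMP1 read 854.9 in vector and 119.8 in PARVB cells. Other probe sets gave -2.19 for CPE, -0.91 for APBA2 and -0.9 for KCTD12. The authors' table calls the vector array absent for NPPB, NUP210, MTSS2, ATN1, FKBP8 and F11R, and the PARVB array absent for CPE, TNC, APBA2 and SPP1. For NPPB, NUP210, ATN1, F11R, CPE, TNC and APBA2 the dimmer array read under the pseudocount, so the size and the order of these differences depend on it.

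Among the lists in 3D collagen, 20 of 21 interferon response genes were above 0 (median 0.88, percentile 100), with IFI27 at 3.05 and OASL at 1.67. Proliferation had 17 of 22 above 0 (median 0.47, percentile 100), with the mitotic kinase PLK1 at 2.2 and the replication licensing factor CDT1 at 1.18, against CDC20 at -0.35 and MCM3 at -0.27. Ribosomal proteins had 19 of 20 above 0 (median 0.84, percentile 100), but quantile normalization put their median at -0.01. The focal adhesion list had a median of 0.36 (percentile 98.7), with TLN1 (talin) at 2.29 and RSU1 at -0.85, and 0.04 without PARVB. On the lower side, matrix proteases had a median of -0.71 (11 of 17 below 0; percentile 0), with SERPINB2 at -1.99 (its PARVB array called absent) beside MMP1, against PLAT at 0.95. Hypoxia had 18 of 19 below 0 (median -0.65, percentile 0), with LOX at -1.76 and ADM at -1.56. Cholesterol synthesis had 12 of 13 below 0 (median -0.66, percentile 0.2), with STARD4 at -1.28 and INSIG1 at -1.17. At least 2-fold different were 2171 probe sets (7.95%), 1395 higher and 776 lower. Quantile normalization gave 1428 (772 higher, 656 lower), and the authors' table calls 1966 increased and 3719 decreased.

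In Matrigel the proliferation genes were lower with PARVB, while interferon, epithelial, lipid and matrix genes were higher. In the proliferation list 20 of 22 members were below 0 (median -0.52, percentile 0), with CDC20 at -0.87 and CCNA2 (cyclin A2) at -0.86. Among single genes HELLS, a chromatin remodeler of dividing cells, was lower by -3.01, the cell cycle transcription factor E2F3 by -2.8 and FANCD2, a DNA repair protein, by -2.67; the other HELLS probe set gave -0.09. EIF5A (-3.13), TNC (-3.05), CHD2 (-2.61), RPL14 (-2.61) and ETV5 (-2.57) were also among the 8 lowest, and the other probe sets of EIF5A, CHD2 and ETV5 averaged -0.66, -0.46 and -0.32. The highest was CCDC3 (3.53), which read 27.5 in vector and 454.3 in PARVB cells, followed by GSN, the actin-severing protein gelsolin (2.97), ALDH3B1 (2.72), AKR1C2, a steroid-metabolising reductase (2.7), TRIB1 (2.69), DNAH2 (2.64), LOC653879, named as similar to a complement C3 precursor (2.63), and the interferon-induced LY6E (2.57). Other probe sets gave 1.2 for GSN, 0.84 for ALDH3B1 and 1.79 for AKR1C2. The authors' signal log ratios of the 8 highest ran from 1.3 for AKR1C2 to 3.9 for TRIB1. The authors' table calls 8 of these 16 probe sets absent on both arrays, so their differences rest on signals not called above background: CCDC3, GSN, TRIB1, DNAH2, LOC653879 and LY6E among the 8 highest, and RPL14 and ETV5 among the 8 lowest. The vector array was called absent for ALDH3B1 and AKR1C2, and the PARVB array for TNC, HELLS, E2F3, FANCD2 and CHD2.

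Among the lists in Matrigel, all 8 epithelial genes were above 0 (median 0.78, percentile 100), with KRT7 at 1.4 and the tight junction gene CLDN4 at 1.04, and so were 20 of 21 interferon response genes (0.73, percentile 100), with IFI27 at 1.76 and IFIT2 at 1.62. The PPARG target list had 10 of 12 above 0 (0.61, percentile 100), with PPARG at 2.29 and PDK4, a brake on glucose oxidation, at 1.61. Fatty acid synthesis had a median of 0.55 (percentile 99.9), with FASN at 1.04 and ELOVL6 at 0.98, and matrix components of 0.49 (percentile 99.9), with AGRN at 1.55 and FN1 (fibronectin) at 1.13 against TNC. Cytokines stood at 0.39 (percentile 99.2), with ICAM1 at 1.41, matrix proteases at 0.38 (percentile 99.7), with the urokinase receptor PLAUR at 1.04, focal adhesion genes at 0.35 (percentile 99.5), with ACTN4 at 1.25, and mesenchymal genes at 0.34 (percentile 98.3, and 96.5 with quantile normalization). The focal adhesion list holds the transfected gene PARVB itself (0.82 in Matrigel). The vector array was called absent for PPARG and IFI27, and both arrays for PDK4 and ICAM1. The authors' signal log ratios differed in size from these values. They were smaller for ELOVL6 (0.3), PLAUR (0.6), AGRN (0.7), FN1 (0.7), ICAM1 (1), PDK4 (1.1) and PPARG (2). For FASN (1), CLDN4 (1) and IFIT2 (1.6) they were close, and for KRT7 (1.7) and IFI27 (2) larger. At least 2-fold different were 1303 probe sets (4.77%), 685 higher and 618 lower. Quantile normalization gave 2196, more than the 1428 it gave in 3D collagen, so the order of both 3D cultures turned with the scaling. The authors' table calls 815 increased and 2032 decreased.

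**Figure D2:**
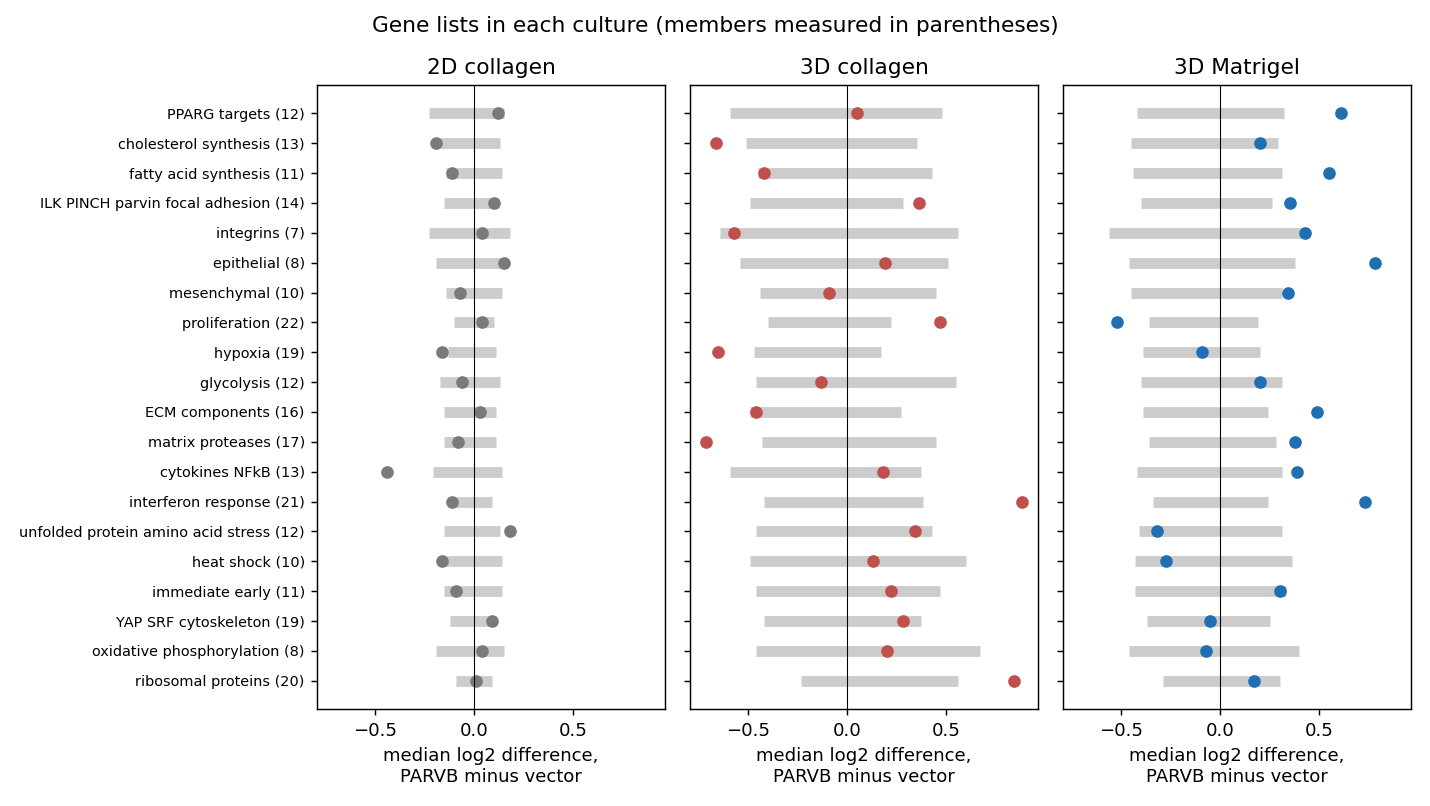
Median log2 difference between PARVB and vector cells (x axis) of the 20 gene lists (y axis, members measured in parentheses) on 2D collagen, in 3D collagen and in Matrigel; dots are the list medians and grey bars the central 95% of 10000 random lists of the same size and signal. The interferon response dot lies right of its bar in both 3D cultures (0.88 and 0.73), and the proliferation dot lies right of it in 3D collagen (0.47) and left of it in Matrigel (-0.52); the ribosomal protein dot in 3D collagen (0.84) moves to -0.01 with quantile normalization.

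Of 60 list medians, 21 lay outside the random lists, 14 above and 7 below. Chance alone would put about 3 there if the lists, and the genes within a list, were independent. The estimated correlation within a list ran from -0.1 (oxidative phosphorylation) to 0.78 (ribosomal proteins). Genes that move together bring more medians outside, so 21 beside 3 is no evidence against chance. For 6 lists the median lay within the random lists in each culture. On 2D collagen, in 3D collagen and in Matrigel these medians were 0.04, -0.57 and 0.43 for integrins, -0.06, -0.13 and 0.2 for glycolysis, -0.16, 0.13 and -0.27 for heat shock, -0.09, 0.22 and 0.3 for immediate early genes, 0.09, 0.28 and -0.05 for YAP and SRF targets, and 0.04, 0.2 and -0.07 for oxidative phosphorylation; in 3D collagen heat shock and oxidative phosphorylation turned to -0.09 and -0.19 with quantile normalization.

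The study compared its gene lists among the cultures by Venn diagram. At least 2-fold different the same way in the 3 cultures were 5 probe sets: CSF2RA, RBPMS and an unnamed one (242473_at; 1.09, 1.09 and 1.31) higher, and TNC and CPE lower. Independent lists would share 0.271 and 0.167. In Matrigel the probe sets of CSF2RA and CPE were called absent on both arrays. On 2D collagen the other probe sets past the filter gave -0.1 and -0.15 for CSF2RA, 0.48 and 0.66 for RBPMS and -0.14 for CPE. In Matrigel that of TNC gave 0.08. Of the 5, the authors call only TNC changed in the 3 cultures. CSF2RA and CPE are not listed on 2D collagen, RBPMS is not listed in Matrigel, and 242473_at is listed in no culture. The 3D cultures shared 97 higher and 44 lower probe sets, where independent lists would share 35 and 17.6, and 52 went opposite ways, where 51.1 would. The 2D and 3D collagen pairs shared 33 and 23 (10.8 and 7.39 if independent), while 33 went opposite ways (19.3). On 2D collagen and in Matrigel 12 and 18 were shared (5.29 and 5.89), while 32 went opposite ways (11.3). In the authors' tables, 10 increased and 87 decreased probe sets are common to the 3 cultures (0.324 and 3.33 if independent), and 202 and 555 to both 3D cultures (29.3 and 138). Common to 2D and 3D collagen are 51 and 350 (21.7 and 89.4), and to 2D collagen and Matrigel 32 and 246 (9 and 48.9). Opposite ways in the authors' tables went 202 between 2D and 3D collagen (88.3), 187 between 2D collagen and Matrigel (42) and 213 between both 3D cultures (129). The expected numbers for the authors' tables were taken over 54613 probe sets, dim ones included, and those for the 2-fold lists over 27297. Over fewer probe sets the same lists would have larger expected numbers. Whether overlaps in the authors' tables lie above those of independent lists can depend on that choice, so no conclusion is drawn from them. Among the 2-fold lists, the opposite overlaps of 2D collagen with either 3D culture also lay above those of independent lists. The opposite overlap of both 3D cultures was close to that number (52 against 51.1). The observed overlaps were not tested, since all probe sets come from the same arrays.

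Between cultures, most genes of the cholesterol synthesis, epithelial, hypoxia, cytokine and interferon lists rose in 3D collagen relative to 2D collagen, and 5 of 22 proliferation genes fell. As lists, none of these passed with an estimated correlation (adjusted p = 0.541, and an adjusted p = 0.692 for proliferation). The median of all probe sets differed by -0.21 between these cultures, so changes are given relative to it, with 2 arrays per culture. Not relative to it are the limma tests and the counts of genes and probe sets that rose or fell. The same holds for the log2 differences of other probe sets and of the named ones in parentheses beside them. The adjusted p of RARRES2, for example, is that of a difference of 3.82. Folds are of the signal plus the pseudocount of 13. The secreted chemoattractant RARRES2 rose 16.4-fold (log2 4.03, SE 0.39, limma adjusted p = 0.00359), the long noncoding RNA UCA1 15.6-fold and MALAT1, another, 12.6-fold. S100A4, a calcium-binding protein, rose 12.1-fold, and TMEM38A, CLIC3, SQSTM1, TMC8, AQP3 and the phosphatase DUSP1 rose between 11.4-fold and 9.59-fold. FAM76B fell 12.7-fold (log2 -3.66, SE 0.44, adjusted p = 0.00394), the chromatin protein HMGA1 11.2-fold, TMPO, a nuclear lamina protein, 9.4-fold, ARHGDIA 7.75-fold, DCBLD2 7.16-fold, the cell cycle kinase CDK6 6.76-fold, DLEU2 5.41-fold and NFYA 5.31-fold. AHNAK and ASXL2 fell 7.27-fold and 6.86-fold at the named probe set, but another probe set of each gave log2 differences of 0.4 and 0.26. Other probe sets also gave smaller falls: log2 -2 and -1.14 for TMPO (-3.45 at the named one), -2.5 and -0.86 for ARHGDIA (-3.17), -0.4, -1.41 and -1.33 for CDK6 (-2.97), and -1.6, -0.68 and -1.7 for NFYA (-2.62). SQSTM1 gave 1.62 and 0.59 (3.16), while DLEU2 gave -2.56 (-2.65) and MALAT1 from 2.99 to 3.44 (3.44). In the lower culture several genes read near or under the pseudocount, which then sets the size of their fold. On 2D collagen these were RARRES2 (9.2 in vector and 16.8 in PARVB cells), TMEM38A (18.9 and 3.3) and TMC8 (15.6 and 14.8). In 3D collagen they were FAM76B (16.3 and 17.5), CDK6 (11.4 and 0.4), DLEU2 (6.3 and 11), NFYA (48.7 and 3.2) and AHNAK (16.8 and 2.3, called absent on both arrays). MALAT1, at 150.6 and 82.9, was called absent on both 2D collagen arrays. In all 20 genes the vector and the PARVB arrays moved the same way.

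By list, camera called 8 lists higher and 1 lower in 3D collagen, and with an estimated correlation none of these 9 calls held (adjusted p = 0.541, and an adjusted p = 0.692 for proliferation). At the preset correlation, 12 of 13 cholesterol synthesis genes rose and 0 fell (camera adjusted p = 1.11e-09), with HMGCS1 at 2.68 and SC5D at 2.5 relative to the median, and LSS at 0.44 did not pass. Of 21 interferon response genes 12 rose (adjusted p = 5.41e-07), with MX1 at 2.3 and ISG15 at 2.26, and of 13 cytokine and NF-kB genes 9 rose (8.1e-05), with SOD2 at 3.26 and NFKBIA at 2.73. Epithelial genes rose in 7 of 8 (0.000293), with KRT7 at 2.34 and CLDN7 at 2.07, and hypoxia genes in 11 of 19 (0.000332), with MXI1 at 2.03 and NDRG1 at 2.02. Fatty acid synthesis (4 of 11 rose; 0.000866), PPARG targets (4 of 12 rose and 1 fell; 0.0208) and the unfolded protein and amino acid stress list (4 of 12 rose and 1 fell; 0.0305) were also higher, and proliferation was lower (5 of 22 fell; 0.00402), with CCNA2 at -1.35 and RRM2 at -1.23. Adjusted over the list alone, 12 cholesterol, 13 interferon, 9 cytokine, 7 epithelial, 12 hypoxia, 6 fatty acid, 4 PPARG target and 4 stress genes rose. In the same adjustment 5 proliferation genes, 1 hypoxia, 1 PPARG target and 1 stress gene fell. With quantile normalization the PPARG target (0.0525) and stress (0.106) calls ended.

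In all, 8507 probe sets passed, 2588 higher and 5919 lower in 3D collagen. Of the 5787 named ones, 704 were higher and 838 lower, so they leaned less to the lower side. A named gene above the median of all probe sets therefore need not stand above the other named genes. Quantile normalization gave 3075 (1357 higher, 1718 lower). Leaving out the vector or the PARVB array of 2D collagen gave 2141 and 1849, and leaving out the vector array of 3D collagen gave 4299. Culture and any day or batch of the arrays cannot be told apart, and the 3D collagen arrays had the highest ACTB ratios, 1.39 and 2.09.

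Matrigel and 3D collagen, the cultures on which the study put its weight, differed most. Relative to the overall median difference of 0.23, UCA1 fell 24.7-fold in Matrigel (log2 -4.62, SE 0.42, adjusted p = 0.000358), DUSP1 21.9-fold, the glycogen phosphorylase PYGB 21-fold and MMP1 20.1-fold. The cytoskeletal linker DST fell 18.4-fold, PPP1R15A, a stress-induced phosphatase subunit, 16.4-fold, ICAM2 15.4-fold, KISS1 14.9-fold, and LOC645166 and the histone methyltransferase EHMT2 14.7-fold each. MGC10955 rose 13.1-fold (log2 3.71, SE 0.23, adjusted p = 0.000309), PPARA, a nuclear receptor of fatty acid oxidation, 12.2-fold, FAM76B 11.5-fold, CCDC13 10.8-fold, HLA-DRA, an antigen-presenting molecule, 9-fold, SNORA65 8.29-fold, NUP58 7.75-fold, DLEU2 6.68-fold and LOC440552 6.45-fold. AHNAK rose 6.63-fold at the named probe set, and its other probe set gave a log2 difference of -0.02. As above, the limma tests, the counts and the log2 differences of other probe sets, with those of the named ones beside them, are not relative to the median. The adjusted p of MGC10955, for example, is that of a difference of 3.93. Other probe sets gave smaller falls for DST (log2 -1.19, -1.12, -1.2 and -1.03, where the named one had -3.97), ICAM2 (-0.82 against -3.72) and PPP1R15A (-2.29 against -3.81). They also gave smaller rises for NUP58 (0.93 against 3.18), DLEU2 (1.89 against 2.97) and LOC440552 (2.39 against 2.92). Here too the pseudocount sets the size of the fold where the lower culture was dim. In Matrigel MMP1 read 7.8 in vector and 5.9 in PARVB cells, EHMT2 12.5 and 8.2, ICAM2 6.8 and 14.3, KISS1 19.2 and 21, and DST 28.7 and 17.9. PYGB, at 25.6 and 52.8, was called absent on both arrays. In 3D collagen MGC10955 read 1.8 and 5.5, PPARA 0.9 and 18.4, FAM76B 16.3 and 17.5, CCDC13 4.2 and 25.7, HLA-DRA 23 and 5.5, SNORA65 1.5 and 35.3, NUP58 45.5 and 10.3, DLEU2 6.3 and 11 and AHNAK 16.8 and 2.3. Of these MGC10955, PPARA and AHNAK were called absent on both 3D collagen arrays. CCDC13, at 348.6 and 279.6, was called absent on both Matrigel arrays.

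By list, camera called 4 lists lower in Matrigel, and with an estimated correlation none of these calls held (adjusted p = 0.922). At the preset correlation, 11 of 12 unfolded protein and amino acid stress genes fell and 0 rose (camera adjusted p = 0.000402), with CEBPB at -2.72 and PPP1R15A at -2.52 relative to the median. Of 13 cytokine and NF-kB genes 9 fell and 1 rose (0.00344), with SOD2 at -3.85 and NFKBIA at -3.42 against CCL5 at 1.7. Of 8 epithelial genes 7 fell (0.0317), with CLDN4 at -1.75 and SPINT2 at -1.65, and of 20 ribosomal protein genes 13 fell (0.0188), with RPS15 at -1.69. Adjusted over the list alone, 11 stress, 9 cytokine, 7 epithelial and 13 ribosomal genes fell and 2 cytokine genes rose. With quantile normalization the epithelial call ended (0.134) and the ribosomal list turned to the higher side (0.939). In all, 14668 probe sets passed, 9403 higher and 5265 lower in Matrigel. The 5787 named ones had the opposite balance, 980 higher and 1287 lower. A named gene below the median of all probe sets therefore need not stand below the other named genes. Quantile normalization gave 5530 higher and 5480 lower, so the excess of higher probe sets depends on the scaling. Here too culture and any day or batch of the arrays cannot be told apart, and the ACTB ratios of 1.39 and 2.09 in 3D collagen stood against 1.05 and 1.1 in Matrigel.

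Matrigel against 2D collagen gave 7931 probe sets, 4891 higher and 3040 lower in Matrigel, and 2514 and 3451 with quantile normalization. Of the 5787 named ones 409 were higher and 753 lower. The overall median differed by 0.09, and culture and batch are confounded here as well. Camera called 5 lists, and with an estimated correlation none of the 5 calls held (adjusted p = 0.833). At the preset correlation, of 13 cholesterol synthesis genes 11 rose and 0 fell (camera adjusted p = 2.62e-11), of 19 hypoxia genes 8 rose (7.1e-05) and of 21 interferon genes 3 rose (0.00495). Of 22 proliferation genes 10 fell (0.000694) and of 12 unfolded protein and amino acid stress genes 5 fell (0.0323). Adjusted over the list alone, 11 cholesterol, 10 hypoxia and 0 interferon genes rose, and 11 proliferation and 5 stress genes fell. With quantile normalization the proliferation (0.0645) and stress (0.114) calls ended. Leaving out 1 array moved the count to between 759 without the PARVB array and 2038 without the vector array of 2D collagen, or to 3189 and 4102 without the PARVB or vector array of Matrigel.

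Markers of other cell types gave little to compare, since few are named in the files. No fibroblast or adipocyte marker could be tested. Of 2 named leukocyte markers, both called increased in 3D collagen by the authors, only CD8A passed the filter. It had PARVB differences of 0.42, 1.79 and 1.31 in the 3 cultures. The endothelial markers ESAM and ROBO4 had a median of -0.02, 0.78 and 0.38.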

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

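Of the tests below, the detection calls and those on RNA quality and on other splits of the arrays were chosen after the results were seen; those on scaling, dim probe sets and the pseudocount were written down after the patterns themselves but before the values of these tests were seen.

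The PARVB difference of 8 named genes went at least 2-fold up in 1 culture and at least 2-fold down in another. With 1 array per group these differences between cultures were not tested. GSN was higher in Matrigel (2.97) and lower in 3D collagen (-1.64), a gap of 4.61 on the log2 scale, and LOC653879 likewise (2.63 and -1.59, a gap of 4.22). RPL14 was higher in 3D collagen (1.55) and lower in Matrigel (-2.61), a gap of 4.16. AKR1C2 was higher in Matrigel (2.7) and lower on 2D collagen (-1.32), a gap of 4.02. CFAP45 (1.15 and -1.95, a gap of 3.1) and ADM (1.15 and -1.56, a gap of 2.71) were higher on 2D collagen and lower in 3D collagen, and NUDT14 the other way round (1.14 in 3D collagen and -1.59 on 2D collagen, a gap of 2.73). DCBLD2 was higher in Matrigel (1.23) and lower in 3D collagen (-1.27), a gap of 2.5. Each gap is between the highest and the lowest culture. In the remaining culture ADM (-1.26 in Matrigel) and GSN (-1.13 on 2D collagen) were also at least 2-fold lower. AKR1C2 (0.43 in 3D collagen), CFAP45 (-0.2 in Matrigel) and DCBLD2 (-0.26 on 2D collagen) stayed under 2-fold there. The authors' tables call the probe sets of GSN, LOC653879 and RPL14 absent on both Matrigel arrays and those of CFAP45 and NUDT14 absent on both 2D collagen arrays, so 1 side of each of these 5 gaps rests on signals not called above background. AKR1C2 and ADM were called present on at least 1 array in both cultures compared. DCBLD2 has calls in 3D collagen only, where its PARVB array was called absent. Other probe sets gave -0.26 in 3D collagen and 1.2 in Matrigel for GSN, and -1.27 on 2D collagen and 1.79 in Matrigel for AKR1C2.

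The medians of 3 lists lay above the random lists in 1 culture and below them in another, again without a test of the difference. Matrix proteases differed by 1.09 between Matrigel (0.38) and 3D collagen (-0.71), and cytokines and NF-kB targets by 0.83 between Matrigel (0.39) and 2D collagen (-0.44). Proliferation differed by 0.99 between 3D collagen (0.47) and Matrigel (-0.52).

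The turn of the proliferation list is the pattern that bears most on growth. Scaling of the arrays and the pseudocount are argued against as whole causes, since the gap between both medians was 1.01 after quantile normalization and 1.01 with a pseudocount of 1, outside the random lists in both cultures each time. For the lower values in Matrigel, the control probe sets showed little difference in RNA quality. The ACTB 3' to 5' ratio of the PARVB array over the vector array was 0.07 in log2, within the SD of the 3 vector arrays (0.22). That of GAPDH was 0.07 against an SD of 0.12. These SDs are between cultures and not between repeat arrays, and the 3D collagen array widens that of ACTB, so they cannot decide the question. For the higher values in 3D collagen RNA quality stays open, since the same log2 ratios were 0.59 and 0.54. With 1 pair of arrays and no probe positions, RNA quality and the PARVB difference cannot be told apart there. An effect of PARVB on cycling that depends on the matrix, and unequal density of the cultures at harvest, may each also account for the turn of this list and were not tested.

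The 3D collagen pair had more probe sets at least 2-fold different than the 2D collagen pair (2171 against 471). Scaling is argued against as the whole cause, since the number after quantile normalization was still 3.29 times that of 2D collagen (1428 against 434), and so is noise of dim probe sets, since among the 13641 brightest probe sets the share was 12.52 times as large (5.6% against 0.45%). RNA quality of the PARVB array stays open: its ACTB 3' to 5' ratio was 2.09, where the highest vector array had 1.39, and its GAPDH ratio was 1.45, where the highest vector array had 1. With 1 pair per culture it cannot be told apart from a larger response to PARVB in a collagen gel, which was not tested either.

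The control probe sets themselves stand outside the comparisons, and besides the values of 2.09 and 1.45, the GAPDH ratio of the PARVB array in Matrigel (1.01) was above the highest vector array (1), by the last digit only.

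Splitting the 6 arrays in other ways into 3 and 3 makes 10 splits, too few for a share under 0.05. The real split of PARVB against vector gave 0 probe sets past the adjusted threshold and the highest other split gave 1. Among the 4 splits that part all 3 pairs, the real split had 1661 probe sets with an unadjusted p under 0.05 and the others 740, 813 and 1420; the remaining splits part 1 pair only, and 2 of these had 4128.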

How the results depend on the processing

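The alternatives chosen after seeing the data were the fits without both arrays of a culture, 1 probe set per named gene, the focal adhesion list without PARVB, the overlap without the 3D collagen pair, and the scaling and pseudocount runs of the numbers of named genes and of lists that went opposite ways between cultures. The pseudocount and the filter decide how many probe sets near background reach 2-fold, and the scaling moved the counts within a culture too. Except where a setting tests fewer probe sets or arrays or changes the threshold, the cause was not tested.

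The PARVB term gave 0 probe sets in limma under all 12 alternatives, with 902 to 2961 at an unadjusted p under 0.05 where the culture block was kept; without the block that pairs the arrays of a culture it gave 0, with 63. For 3D against 2D collagen the count was 4091 above the 75th percentile, 3075 with quantile normalization and from 1849 to 6859 without 1 array. For Matrigel against 3D collagen it was 26989 without a filter and 6056 above the 75th percentile, and from 10985 to 12384 without 1 array. For Matrigel against 2D collagen it was 12171, 3079 and from 759 to 4102. Without both Matrigel arrays the first count was 8917, and without both 3D collagen arrays the last was 9839. With 1 probe set per named gene the 3 counts were 8334, 14309 and 8058.

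The number of probe sets at least 2-fold different on 2D collagen, in 3D collagen and in Matrigel was 113, 801 and 586 with the pseudocount at the median, 2749, 4751 and 3720 without a filter, 61, 764 and 437 above the 75th percentile, 2240, 7260 and 4741 at 1.5-fold, 89, 445 and 299 at 3-fold, and 1916, 5685 and 2847 in the authors' tables. A pseudocount of 1 gave 783 on 2D collagen and 3502 in 3D collagen, and quantile normalization gave 1428 in 3D collagen and 2196 in Matrigel. The 5 probe sets shared by the 3 cultures became 12 with a pseudocount of 1, 2 with the pseudocount at the median, 12 without a filter, 0 above the 75th percentile, 2 with the mean over a gene's probe sets, 82 at 1.5-fold, 0 at 3-fold, 97 in the authors' tables and 30 without the 3D collagen pair. The PARVB difference in 3D collagen was 2.17 with quantile normalization and 3.51 with a pseudocount of 1.

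With an estimated correlation 0 lists were called in each of the 4 comparisons, against 6, 9, 4 and 5. That setting tests on 2 residual degrees of freedom, so its lack of calls cannot decide whether those at the preset correlation hold. With quantile normalization 2 lists were called between Matrigel and 3D collagen, and the ribosomal proteins turned to the higher side (adjusted p = 0.939); their median in 3D collagen turned to -0.01. Without a pair, from 4 to 8 lists were called for PARVB. Of the list medians outside the random lists, 18 of 21 were outside the same way with quantile normalization and 21 with a pseudocount of 1. Among named genes the sign held in 111 of 111 values with quantile normalization, 109 of 109 with a pseudocount of 1 and 44 of 48 with the average of the other probe sets, where AHNAK (0.4 between 3D and 2D collagen and -0.02 between Matrigel and 3D collagen), ASXL2 (0.26) and TNC in Matrigel (0.08) turned. Taken singly, other probe sets also turned for CSF2RA on 2D collagen (-0.1 and -0.15) and for VDR (0.12) and CHD2 (0.1) in Matrigel, and 1 of LNPEP stood at 0 in Matrigel. Named genes 2-fold opposite between cultures numbered 10 and 12 with quantile normalization and a pseudocount of 1, against 8.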

Other observations

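The PARVB difference of interferon response genes was unlike between 2D collagen and the 3D cultures. Of the 41 genes of this list 23 carry a name, and the authors called each of these changed in a 3D culture. No such choice was made on 2D collagen, so the contrast is in part set by the naming. With PARVB, IFI27 differed by -0.54 on 2D collagen, 3.05 in 3D collagen and 1.76 in Matrigel, and the list as a whole had 6, 20 and 20 of its 21 members above 0. MX1, an antiviral GTPase, was the highest of them on 2D collagen (0.36) and stood at 0.1 in Matrigel. In vector and PARVB cells together all 21 members lay above the overall median difference between 3D and 2D collagen. That was also so for all 20 ribosomal protein, all 13 cholesterol synthesis and all 8 epithelial genes, but for only 5 of 22 proliferation genes. This median is of all probe sets, of which 2588 were higher and 5919 lower in 3D collagen. The named ones, from which the lists come, leaned less to the lower side (704 and 838), so lying above it is not particular to a list. Of the 21 interferon genes 12 rose (camera adjusted p = 5.41e-07 for the list). With an estimated correlation the list did not pass (adjusted p = 0.541). The PARVB array in 3D collagen is the one with ACTB and GAPDH 3' to 5' ratios of 2.09 and 1.45, so RNA quality stays open there, and the vector array in Matrigel was called absent for IFI27. How the PARVB difference itself varied between cultures was not tested.

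Sterol and fatty acid genes had PARVB differences of unlike sign in the 3D cultures, and the gap between both cultures was not tested. On the 3D collagen side the PARVB array had ACTB and GAPDH 3' to 5' ratios of 2.09 and 1.45, so RNA quality stays open there too. Cholesterol synthesis genes were below 0 in 12 of 13 members in 3D collagen and above 0 in 9 of 13 in Matrigel, with medians of -0.66 and 0.2. Fatty acid synthesis genes were below 0 in 9 of 11 and above 0 in 9 of 11, with medians of -0.42 and 0.55, and FASN, the fatty acid synthase, was above 0 in both (0.78 and 1.04). Integrins were below 0 in 6 of 7 members in 3D collagen and above 0 in 5 of 7 in Matrigel, both within the random lists. Cholesterol synthesis in Matrigel (percentile 93.5) and fatty acid synthesis in 3D collagen (percentile 3.8) also lay within the random lists, so only 1 side of each of these gaps was outside them. The medians had the same signs with quantile normalization: -0.57 and 0.25 for cholesterol synthesis, -0.4 and 0.61 for fatty acid synthesis and -0.44 and 0.4 for integrins.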
